A study of Mus musculus with 2 samples.

How the data were processed

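RNA from CD4+ T cells was profiled on 1-colour miRNA arrays, 1 array for spleen and 1 for the gut lamina propria, the connective layer under the intestinal epithelium. Both samples came from female C57BL/6 mice aged 10 weeks that carry 1 working copy of the gene for interleukin 10, an anti-inflammatory cytokine. Per the labels' protocols, lamina propria lymphocytes were freed with collagenase, CD4+ T cells of both tissues were isolated on magnetic beads, and the extracted RNA was labelled with the dye Hy5. Collagenase is mentioned for the lamina propria only, so tissue and dissociation cannot be told apart. How many mice stand behind each array is not given in the sources used here.

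The deposited values are linear intensity values in arbitrary units, 1 column per array. The authors left a row blank where no value is given, and no listed value was 0 or less. The background subtraction, detection rule and scaling behind these intensity values are not given in the sources used here. Listed values were crowded just above the lowest one on each array: 162 of 516 spleen values and 157 of 378 lamina propria values lay within 2 times of it. The lowest values were 1.39 in spleen and 2.88 in lamina propria.

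The table names its 739 rows by MIMAT accessions, which the miRBase registry gives to mature miRNA sequences. Neither the table nor the gene table used here pairs these accessions with miRNA names, and 0 of them could be matched. No row is therefore given a name, a sequence or a genomic position. The 19 lists of miRNAs fixed by name before the data were examined (cell type markers, T cell states, families and clusters) could not be applied, and markers of other cell types were not assessed. Of the rows, 5 carry several accessions; they were kept as single rows under their first accession.

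For each row with a value on both arrays, the log2 ratio of lamina propria to spleen was taken from the deposited values with no further scaling and no pseudocount. With 1 array per tissue there was no replicate error, so no test and no p-value for the tissue difference was possible. Rows were counted by a rule fixed before the data were examined: at least 2-fold higher or lower among the upper 50% of rows by mean log2 level. The rule for single rows, also fixed then, took the 12 highest and 12 lowest ratios in that set, the 10 brightest rows of each array and the 5 brightest rows listed on 1 array. Because accessions alone say little, at most 2 accessions per direction are printed, and the other rows are summarised. Of the 4 printed, the row with the highest ratio and the row with the lowest come from that rule, and the other 2 mark the ends of a run of 15 accessions picked after the values were seen. The grouping of rows by accession number was also chosen after the values were seen.

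Group medians were set against 10000 random lists of the same size, drawn from all rows measured on both arrays within 5 classes of mean level, or 10 as an alternative. Alternatives for the ratios were the median, the 75th percentile, or the total without the 10 brightest rows set equal, quantile normalization, removal of a lowess curve (fraction 0.5), and 1 or 10 added before log2. Other filters and thresholds were all rows, the upper 25%, 1.5-fold and 4-fold. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6. The counting was tested on simulated data: lamina propria values were drawn for the 353 rows from the spleen values with a noise SD of 0.2 (log2). All changed rows in the upper 50% (31, 31 and 28 rows at true log2 changes of 1.5, 2 and 3) were recovered, with 0 false calls. At this noise such changes lie well past the 2-fold cut, so their recovery checks only the counting. No blanks, unequal lowest values or trend with level were simulated. The noise of the real arrays is unknown, so the simulation says nothing of their error.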

Results

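The study asked how miRNA levels differ between CD4+ T cells, the helper lineage of T cells, from the spleen and from the intestinal lamina propria of Il10 heterozygous mice. Each tissue was represented by 1 array, so every value below has n = 1 and no error, and differences between tissues have no replicate check. The number of arrays limits the precision of all values. Of 739 rows on the array, 516 (69.8%) had a value in spleen and 378 (51.2%) in lamina propria. Both arrays listed 353 rows, and 198 rows were listed on neither. Across the 353 shared rows, the log2 intensities of the 2 arrays correlated with a Pearson r of 0.89 and a Spearman rho of 0.80. These coefficients are across rows, which are not independent replicates.

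Among the brighter miRNAs, more were lower than higher in lamina propria CD4+ T cells. Of the 177 rows in the upper 50% by mean level, 73 (41.2%) were at least 2-fold lower in lamina propria than in spleen, 27 (15.3%) were at least 2-fold higher, and 77 (43.5%) were within 2-fold. The median log2 ratio of these rows was -0.59, or 1.5-fold lower in lamina propria, with quartiles of -1.64 and 0.55. Under 4 of the 5 other scalings this median was between -0.20 and -0.12, and it changed sign after quantile normalization, to 0.027. Over all 353 shared rows, with no filter on level, the median was 0.0093, also of the opposite sign. That median over all shared rows was -0.18 with spleen values under 2.88, the lowest value listed in lamina propria, left out. All 53 shared rows so removed were higher in lamina propria, so a fall was built in. The ratios are relative to the deposited scale, on which the summed intensity was 136232 in spleen and 182481 in lamina propria, 1.34 times as much. Setting the medians of the 353 shared rows equal raised every log2 ratio by 0.43 and gave 60 lower and 43 higher rows. The split was 62 lower and 39 higher with the 75th percentiles set equal, and 60 and 47 with the total signal set equal without the 10 brightest rows. It was 48 and 42 after quantile normalization and 44 and 44 after removal of the trend with level. Quantile normalization sets the 2 distributions equal over the 353 shared rows, so a split nearer to even is partly built into it. Removal of the trend centres the ratios near 0 at every level, so a near-even split is built into it. Lower rows outnumbered higher ones on the deposited scale and under the 4 scalings other than removal of the trend. On the deposited scale, by the same 2-fold rule, 54 of the 79 rows numbered 904 or lower were lower and 8 higher. That group was picked after the values were seen. The 14 rows of the run of 15 had 1 lower and 6 higher. The remaining 84 rows had 18 lower and 13 higher, so the excess of lower rows came mainly from the low accession numbers.

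**Figure D1:**
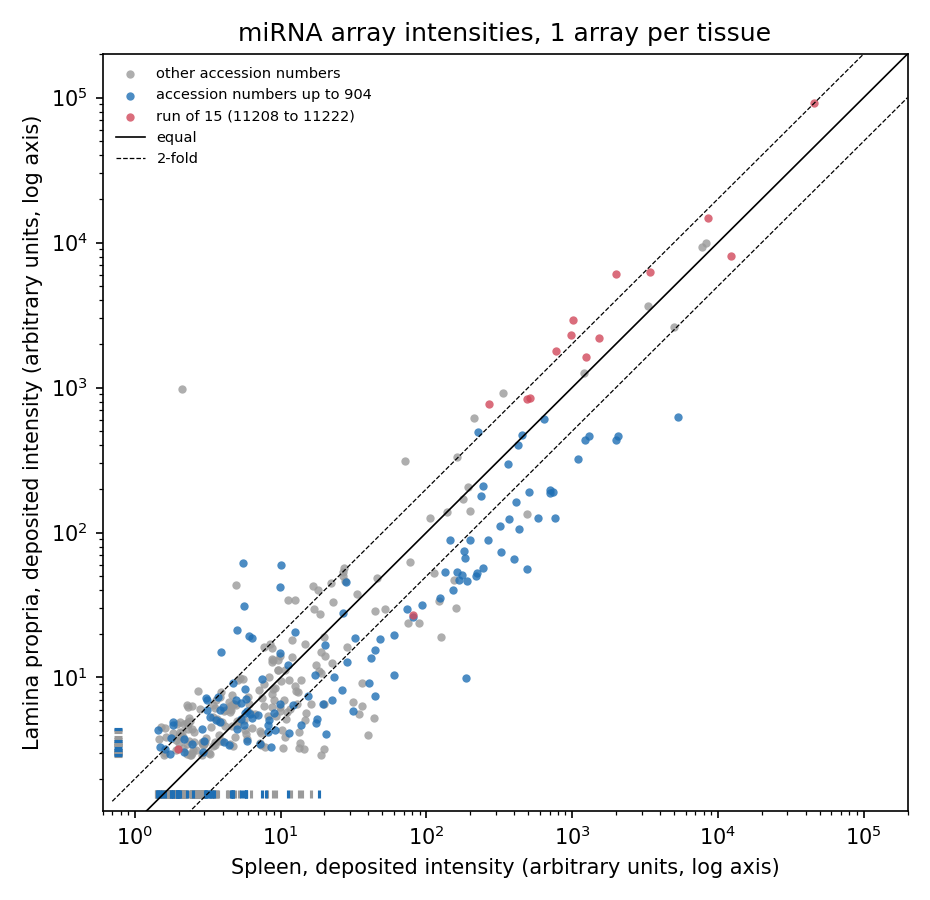
Deposited intensity of each row in lamina propria (y axis) against spleen (x axis), both in arbitrary units on log axes, 1 array per tissue. Each point is 1 of the 353 rows listed on both arrays, marks along the lower and left margins are rows listed on 1 array only, and the dashed lines show 2-fold differences; of the 128 shared rows with accession numbers of 904 or lower, 84 lie below the line of equality and 44 above it.

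The row with the highest ratio, MIMAT0004521, had an intensity of 2.10 in spleen and 984.31 in lamina propria, a log2 ratio of 8.87 (469-fold), or 6.36 with 10 added to both values. Its spleen value was 1.51 times the lowest value listed on that array. Against the lowest value listed in lamina propria, 2.88, its lamina propria intensity was 342-fold higher. The next highest row was 11.1-fold higher in lamina propria, and the remaining rows among the 12 highest lay between 2.95-fold and that value. Most of these 12 were dim in spleen: 10 had spleen intensities under 12, and only 1 exceeded 100.

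The row with the lowest ratio, MIMAT0000210, had an intensity of 187.54 in spleen and 9.97 in lamina propria, a log2 ratio of -4.23 (18.8-fold lower). This ratio was -3.31 with 10 added, -3.33 after removal of the trend with level and -3.36 after quantile normalization. The 12 lowest rows were between 5.73-fold and 18.8-fold lower in lamina propria. Their spleen intensities ran from 34.2 to 5314, above those of 10 of the 12 highest rows. Picking extreme ratios above a set mean level favours low spleen values among the highest rows and high ones among the lowest. This contrast is therefore built into the selection. Their lamina propria intensities ran from 4 to 622.

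A few rows carried most of the signal on both arrays. The brightest row was the same in both tissues, at 45487 in spleen and 92004 in lamina propria, 2.02-fold higher in lamina propria. It alone held 33.4% of the summed intensity in spleen and 50.4% in lamina propria. The 10 brightest rows of each array held 74.6% in spleen and 85.3% in lamina propria, and 8 of them were shared between the tissues. Among the 10 brightest spleen rows, 2 were at least 2-fold lower in lamina propria and 1 was at least 2-fold higher. Among the 10 brightest lamina propria rows, 3 were at least 2-fold higher there and 0 were at least 2-fold lower. Picking the brightest rows of 1 array favours rows that are higher on that array, so each split is partly built in.

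A run of 15 consecutive accessions, MIMAT0011208 to MIMAT0011222, picked after the values were seen, held 4 of the 10 brightest rows in spleen and 6 of the 10 brightest in lamina propria. It includes the brightest row of both arrays, which held 57.8% of the run's intensity in spleen and 65.5% in lamina propria. This run held 57.8% of the summed intensity in spleen and 77.0% in lamina propria. All 15 rows were listed on both arrays, and 13 had spleen intensities over 200. In lamina propria 13 of the 15 were higher and 2 were lower, with a median log2 ratio of 0.79 (1.72-fold higher). The first of the run, MIMAT0011208, had 12376 in spleen and 8114 in lamina propria, a log2 ratio of -0.61. The last, MIMAT0011222, had 3412 in spleen and 6310 in lamina propria, a log2 ratio of 0.89. Ratios within the run spanned 2.997-fold lower to 3.01-fold higher.

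Rows with the lowest accession numbers (904 or lower) went the other way. Registry numbers are given broadly in order of entry, so low numbers tend to mark miRNAs described early. This group too was picked after the values were seen. Their summed intensity was 26723 in spleen and 8969 in lamina propria, 2.98-fold lower, and their share of the signal was 19.6% in spleen against 4.92% in lamina propria. Of 128 such rows on both arrays, 84 were lower and 44 higher in lamina propria. Of the 79 in the upper 50% by mean level, 54 were at least 2-fold lower in lamina propria, 8 were at least 2-fold higher and 17 were within 2-fold. Their median log2 ratio was -1.53 (2.89-fold lower), with quartiles of -1.95 and -0.36, and over all 128 shared rows it was -0.72 (1.65-fold lower). In the upper 50% it was -0.82 after quantile normalization and -0.72 after removal of the trend with level. The 3 brightest of them in spleen had 5314, 2067 and 2000 there, and were 8.54-fold, 4.46-fold and 4.57-fold lower in lamina propria. The summed intensity of these early accessions was 0.339 times that of the run of 15 in spleen and 0.0638 times in lamina propria, a 5.32-fold difference that is independent of a single scaling factor between the arrays. Without the brightest row of the run the 2 values were 0.804 and 0.185, a 4.35-fold difference. The median ratio of all 15 rows of the run was 4.98-fold above that of the early accessions in the upper 50% as deposited, and 2.66-fold above it after removal of the trend with level. Against all 128 shared early accessions it was 2.84-fold higher. The remaining 84 rows of the upper 50% had a median log2 ratio of -0.03, with 18 at least 2-fold lower and 13 at least 2-fold higher.

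**Figure D2:**
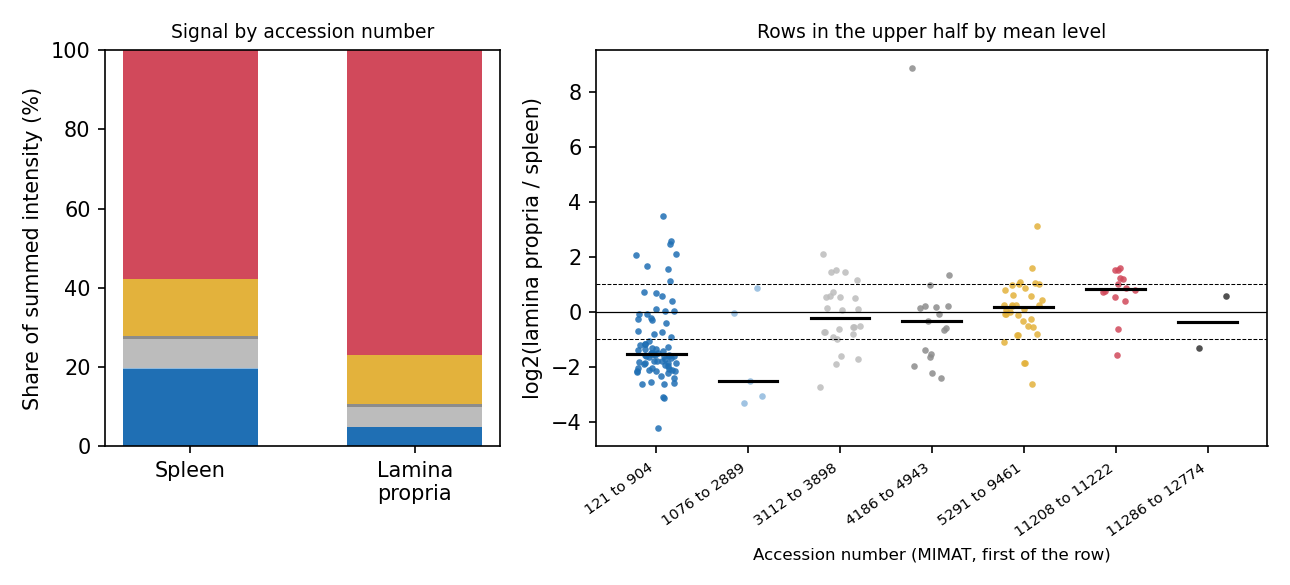
Left, share of the summed intensity of each array (%, y axis) held by rows grouped by accession number, in the colours of the right panel. Right, log2 ratio of lamina propria to spleen (y axis) for the 177 rows in the upper 50% by mean level, by accession number (x axis), with each point 1 row, black bars the group medians and dashed lines 2-fold differences; the median was -1.53 for numbers of 904 or lower and 0.84 for the 14 rows of the run of 15 in this set.

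More rows were listed in spleen alone than in lamina propria alone, 163 against 25. Of the 163, 116 had spleen intensities under 2.88, the lowest value listed in lamina propria, and so no direction could be given for them. The brightest of the 163 had 18.3 in spleen, at least 6.35-fold higher than the lowest value listed in lamina propria, and 14 had a bound of 2-fold or more. The 25 rows listed in lamina propria alone had a median intensity of 3.26 and a maximum of 4.39. Set against the lowest spleen value of 1.39, the maximum was at least 3.16-fold higher in lamina propria. The lowest listed values themselves differed 2.07-fold, so every row listed in lamina propria alone exceeds a 2-fold bound whatever its level, and the number of such rows is not comparable with the 14 for spleen. These bounds are on the deposited scale and assume that a blank means a level under the lowest listed value of that array. With spleen values under 2.88 left out, so that both arrays had the same lowest value, 47 rows were listed in spleen alone and 78 in lamina propria alone, 53 of which had lost a spleen value this way.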

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

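The medians of the upper 50% and by accession group, and the settings without the run of 15 and with one lowest value (also for rows listed on 1 array only, a count planned before), were added after the data were examined. As deposited, the counts at least 2-fold higher and lower were 27 and 73, and the medians (log2) were -0.59 for the upper 50%, 0.79 for the run of 15 and -1.53 for the early accessions. Rows at least 2-fold higher numbered 43 with medians set equal, 42 after quantile normalization, 44 after trend removal, 47 with the trimmed total set equal and 57 over all rows. They numbered 13 in the upper 25%, 41 at 1.5-fold and 8 at 4-fold. Rows at least 2-fold lower numbered 48 after quantile normalization, 44 after trend removal, 46 in the upper 25% and 26 at 4-fold. Trend removal evens the split by construction, and quantile normalization does so in part. The counts over all rows, in the upper 25% and at other folds differ by construction. The lower rows included 60 of the original 73 with medians set equal and 42 after trend removal.

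The median of the upper 50% changed sign after quantile normalization (0.027) and over all rows (0.0093). It was -0.158 with medians, -0.201 with 75th percentiles and -0.121 with the trimmed total set equal, -0.119 after trend removal, -0.430 with 10 added, -1.16 in the upper 25% and -0.732 without the run of 15. The run of 15 moved to 1.22, 1.17 and 1.25 with medians, 75th percentiles and the trimmed total set equal. The early accessions moved to -1.10, -1.15 and -1.07 under these 3, -0.818 after quantile normalization, -0.724 after trend removal, -1.18 with 10 added and -0.721 over all rows. The signs of the run, of the early accessions and of the 4 printed accessions were kept in each setting run for them; the setting with one lowest value leaves out the spleen value of MIMAT0004521. Rows listed on 1 array only became 47 in spleen and 78 in lamina propria with one lowest value. Setting the medians, the 75th percentiles or the trimmed total equal adds 1 constant to every log2 ratio. The changes under these 3 settings follow from that constant. The cause of the other changes was not tested. The list medians planned by miRNA name were not run because no accession could be named. No paired analysis was possible because each tissue has 1 array, and no replicate could be left out. The arrays' signal over background is unknown.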

Other observations

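All tests in this part were chosen after the values they bear on were seen. The other accession groups with over 50 shared rows had medians between those of the early accessions and the run of 15. Rows numbered 5291 to 9461 had a median log2 ratio of 0.38 over 85 shared rows, with 56 higher and 29 lower in lamina propria, at the 98.5th percentile of 10000 random lists matched on level in 5 classes and the 99.7th with 10. In the upper 50% by mean level their median was 0.16, and 24 of 34 rows were within 2-fold. They held 14.4% of the signal in spleen and 12.3% in lamina propria. Rows numbered 3112 to 3898 had a median of 0.10 over 51 shared rows, at the 78.0th percentile with 5 classes and the 72.7th with 10. Rows numbered 4186 to 4943 had a median of -0.01 over 60 shared rows, at the 2.89th percentile with 5 classes of level and the 5.1th with 10. The random lists came from all 353 shared rows, among them the 128 early accessions picked after their low values were seen. A later group can rank high through that pool, so these percentiles are descriptions and not separate support. The run of 15, also picked for its values, lay at the 99.85th percentile with 5 classes and the 96.48th with 10. The random lists could hold the run's own rows, and their median went from -0.61 with 5 classes to 0.14 with 10. These 2 percentiles are therefore also descriptions only. Rows numbered 1076 to 2889 had a median of 0.01 over 11 shared rows, and 3 of the 5 in the upper 50% were at least 2-fold lower in lamina propria. The share of rows listed in lamina propria was 65.2% for the early accessions, 59.1% for numbers 5291 to 9461 and 36.2% for 4186 to 4943. The corresponding shares in spleen were 80.9%, 77.3% and 59.6%.

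The opposite shifts of the run of 15 and of the early accessions were weighed first. The median log2 ratio of the run's 15 rows lay 2.32 above that of the early accessions in the upper 50%, and 1.51 above that of all 128 shared early accessions; both groups were picked for going opposite ways, so this gap is the observation and not evidence for it. A single factor between the arrays cannot make or move such a gap. Of the 2 scalings that change with level, quantile normalization left 1.53 and removal of the trend left 1.41 (bootstrap 95% interval over rows of these arrays 0.68 to 2.22). Over all 128 early accessions they left 1.07 (0.45 to 1.78) and 1.08 (0.50 to 1.97). These 2 scalings shrank the gap and did not remove it. The early accessions made up 44.6% of the upper 50%, so both scalings take in part of the group's own shift. The shrinkage is therefore partly built in and does not measure how much of the gap scaling explains. Both groups were picked from these same ratios, which can inflate the remaining gap and its interval. The bootstrap resampled rows, which are not independent, so the intervals may be too narrow. A difference in scaling as the whole of the gap therefore cannot be ruled out. The lower end of the interval was asked to stay above 0.5, a bound set after the values were seen. Over all 128 early accessions, quantile normalization missed it (0.45). The listed values were not themselves at equal total signal, since their sums differed 1.34-fold. Scaling to equal total signal is a single factor and by itself cannot make the gap. For the low ratios of the early accessions alone, such scaling before background subtraction or blanking, with the run taking more signal, cannot be excluded. Those steps are not given in the sources used here. Labelled fragments of longer RNAs that were more abundant in one preparation may underlie the run; no sequence was matched for its 15 rows, so this, the collagenase step and a tissue difference in miRNA levels cannot be told apart.

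The ratio also changed with level. In 5 equal groups of shared rows by mean level, the median log2 ratio went from 0.71 in the dimmest group to 0.24, -0.53, -0.73 and -0.93 in the brightest. The lower medians of brighter rows were not general: in the upper 50% the early accessions had a median of -1.53, the 14 rows of the run of 15 one of 0.84 and the other 84 rows one of -0.03. The lowest listed value was 2.07 times higher in lamina propria, which may select dim rows that are high there. With spleen values under 2.88 left out, the medians were 0.18, -0.28, -0.53, -0.97 and -0.36, with no steady fall to the brightest group. All 53 shared rows so removed were higher in lamina propria, so the median of the dimmest group had to fall and the selection cannot be told apart from a real difference of dim rows.

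A further hypothesis was that rows with adjoining accession numbers, often entered together, move together. Over 165 pairs of rows with adjoining numbers, outside the run of 15 and after removal of the trend with level, the log2 ratios had a Spearman correlation of 0.28. Shuffling rows within their accession group gave a middle 95% from -0.08 to 0.21 (one-sided permutation p = 0.0019, 10000 shuffles, rows are not independent replicates). Shared transcription, similar sequences that bind each other's probes and neighbouring spots could each give such a correlation, and none of these was tested. The shuffles kept a row's accession group but not its level, so a dependence on level left within groups could also contribute. The highest ratio, that of MIMAT0004521, rests on a spleen value near the lowest listed one and has no repeat measurement here.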
